A study of Mus musculus with 9 samples.

How the data were processed

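Expression was measured by RNA sequencing of total RNA from primary cultured renal cells of wild-type mice, in 3 groups of 3 libraries taken 6 h after treatment. Per the submitters' processing notes, reads were aligned with STAR to mm10, counted with featureCounts and analysed with DESeq2. The deposited table holds raw counts per Ensembl gene for 57010 genes, and per the file headers these were made by featureCounts 2.0.1 at default settings on Ensembl 109 for GRCm39. The intervals in the table settle the build: those of Actb, Vcam1, Gapdh and Eef1a1 do not overlap their GRCm38 positions, and Actb holds 651827 counts in all, so coordinates are given on GRCm39. At these defaults reads that overlap more than 1 gene or align to several places are not counted, and counts are not split by strand. For named genes with over 10% of their exon length shared with another gene, some reads are therefore missing or assigned unevenly.

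Groups and replicate numbers come from the sample titles. Gene symbols were taken from the mouse annotation for 52029 gene identifiers, which hold 99.6% of the counts. Where several identifiers share a symbol, the symbol stayed with the one that has most counts. Total counts were between 14194295 and 20892176 per library, and no 2 replicates were close enough to be copies (chi-square per degree of freedom 1.87 to 6.53 within groups).

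Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by the edgeR filter filterByExpr, which left 14747, and libraries were scaled by TMM factors (0.993 to 1.01). A quasi-likelihood model with a mean per group was fitted to all 9 libraries, with a common dispersion of 0.00161, or a coefficient of variation of 4.01% between replicates. The tests were TNF versus PBS, TNF with ACHP versus TNF, TNF with ACHP versus PBS, and any difference among the 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change was derived from the quasi-likelihood F statistic. CPM values in the text are scaled by TMM and given as mean and SD of 3 libraries, with a gene's own values where counts are small.

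The comparisons, the thresholds, the 26 gene lists, the alternatives and the rule for naming genes were set before the data were examined. The rule names Vcam1, the 8 genes with the largest change in each direction of each comparison among those called, with at least 5 CPM in the higher group and no overlap between both groups, up to 3 called genes with the largest change in each list, and up to 8 genes that rose with TNF, stayed above PBS and were not lower with ACHP. Predicted genes and those named by clone or identifier were left out of the largest changes. Of 624 list genes 487 were tested. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 78 list tests, then with camera at an estimated correlation and with fry. Camera compares a list with all other genes, and fry tests whether the genes of a list move, on balance, in a single direction. At the preset correlation 42 of the 78 tests were called, at the estimated correlation 23, and with fry 47.

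The same fit was tested on simulated data with known changes. It recovered 25 of 50 genes at the smallest change simulated, 38 of 50 changed 1.5-fold, 43 of 50 at 2-fold and 49 of 50 at 4-fold. Of 168 genes it called 13 had no simulated change (7.74%), and for DESeq2 this was 9 of 159. In a simulated comparison without change 2 of 14526 genes were called. A raised list of 30 genes was called and 0 of 50 lists without change were.

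Genes of neurons, astrocytes, oligodendrocytes, choroid plexus, liver, muscle, lung, testis, pancreas and intestine were listed after neural transcripts were noticed in the data, and the counts of each library were summed over each list. Genes that follow the neural transcripts were defined as those at least 4-fold higher in PBS replicates 2 and 3 than in PBS replicate 1 after adding 0.25 CPM. The overlap of comparisons that share a group was set against 20 simulated sets of libraries without change and against independent lists of the same sizes.

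Alternatives set before the data were examined were DESeq2, RLE factors, total counts alone, no filter, a stricter filter (at least 1 CPM in at least 3 libraries), a fit of only the 6 libraries of a comparison, the replicate number as a block, leaving out each library, counts thinned to the smallest library, an adjusted p under 0.01, and an absolute log2 fold change of at least 1. Added after the data were seen were a term for libraries with neural transcripts, the log2 neuron list expression as a covariate, leaving out the genes that follow the neural transcripts, and PBS replicate 1 as the only PBS library. For the latter the spread of the lone library is assumed to equal that of the other groups. No library was left out, and a result for 1 gene that the naming rule selects is not reported.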

Results

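RNA sequencing counts came from primary cultures of kidney cells of wild-type mice, grown from digested whole kidneys and sampled 6 h after treatment. The 3 groups of 3 libraries were PBS, 20 ng/mL TNF, and 20 ng/mL TNF with 1 µM ACHP, an inhibitor of the NF-kB pathway. Total counts per library ran from 14194295 to 20892176. The design addresses whether NF-kB carries the induction of Vcam1 by TNF, and it has no group with ACHP alone. The labels do not say whether the replicates came from separate animals, so each p-value measures only the spread between these libraries.

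Vcam1, which encodes an adhesion molecule that binds leukocyte integrins (ENSMUSG00000027962, chromosome 3, 115903598 to 115923337, GRCm39), rose with TNF and was back near its PBS level when ACHP was present. Its expression was 19.2 ± 1.3 CPM (counts scaled to a common library total, SD, n = 3) with PBS, 93.0 ± 6.99 with TNF and 21.1 ± 2.78 with TNF and ACHP. The log2 fold change was 2.27 (SE 0.08, edgeR adjusted p = 1.0e-13) for TNF versus PBS and -2.15 (SE 0.08, edgeR adjusted p = 2.0e-13) for ACHP versus TNF. Against PBS, the cultures with TNF and ACHP differed by 0.13 (SE 0.09, edgeR adjusted p = 0.52), within the error. The counts behind these values were 266, 371 and 336 with PBS, 1820, 1396 and 1342 with TNF, and 396, 400 and 313 with TNF and ACHP. Leaving out any single library kept the TNF effect between 2.21 and 2.33 and the ACHP effect between -2.26 and -2.07.

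**Figure D1:**
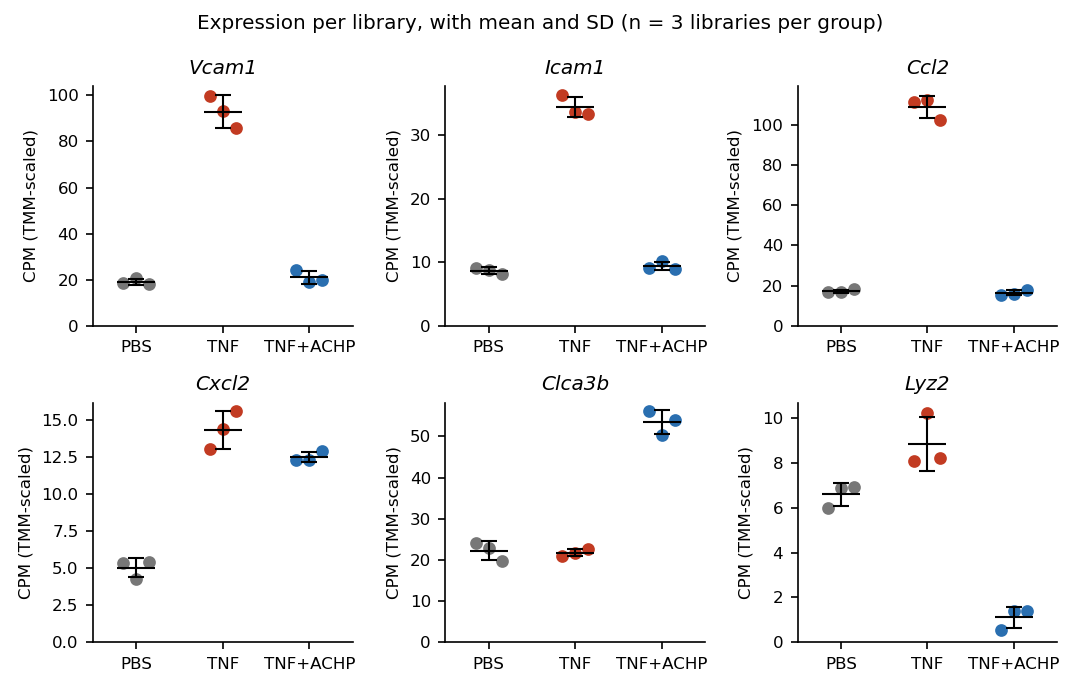
Expression (TMM-scaled CPM) of 6 genes in each library, with the mean and SD of 3 libraries per group. Vcam1, Icam1 and Ccl2 return to the PBS level with ACHP, Cxcl2 stays high, and the group with ACHP is the highest for Clca3b and the lowest for Lyz2.

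TNF raised genes that recruit and hold leukocytes. Ccl2, a monocyte chemokine, went from 17.2 ± 0.84 to 108.6 ± 5.53 CPM (SD, n = 3, log2 fold change 2.66, SE 0.06, edgeR adjusted p = 2.4e-16). Icam1, a second adhesion molecule for leukocytes with 11.7% of its exon length shared with other genes, went from 8.68 ± 0.53 to 34.4 ± 1.63 CPM (1.99, SE 0.08, edgeR adjusted p = 1.8e-12). Ccl20, a chemokine for T cells and dendritic cells, rose by 1.71 on the log2 scale, and Mmp9, a gelatin-degrading protease, by 1.66, from 55.7 ± 5.18 to 177 ± 5.21 CPM. Feedback inhibitors of NF-kB rose as well: Nfkbia by 1.14, Nfkbie by 0.96 and Tnfaip3 by 0.95. Mmp3, a stromelysin, had 0, 8 and 3 counts in the PBS libraries and 58, 67 and 57 in the TNF libraries. Over all 14747 genes tested by edgeR, 488 were higher and 429 lower with TNF, 46 and 9 of them by at least 2-fold, and the median change of the called genes was 0.26 upward and -0.26 downward. The unadjusted p was under 0.05 for 2763 genes.

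Several genes of the collecting duct and of other epithelial cells fell with TNF. Elf5, a transcription factor of collecting duct cells, went from 5.74 ± 0.40 to 2.10 ± 0.24 CPM (SD, n = 3, log2 fold change -1.46, SE 0.18, edgeR adjusted p = 3.2e-05). Cldn8, a tight junction gene of the collecting duct, fell by 1.01 on the log2 scale, and the genes of the epithelial sodium channel subunits, Scnn1a (-0.49) and Scnn1b (-0.74), fell too. So did Psca (-1.04), Sprr2g (-0.86) and Chdh, an enzyme of choline breakdown (-0.75). Ggt1, an enzyme of the proximal tubule brush border, fell by 0.57. Col1a1, a fibrillar collagen, fell by 0.39. Hsd11b2, which protects the mineralocorticoid receptor in the collecting duct, rose by 0.59, and the list of distal segments had 1 higher and 3 lower of 12 (1 and 5 adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.14 with an estimated correlation, fry adjusted p = 0.014). The number of called genes depended on the TNF libraries: without TNF replicate 1 it was 252 higher and 216 lower, without TNF replicate 2 it was 275 and 224, and without TNF replicate 3 it was 318 and 279.

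Of the 26 gene lists fixed in advance, those of inflammation moved up with TNF. Among 19 chemokines tested 9 rose and 1 fell (11 and 1 adjusted over the list alone), with a median log2 fold change of 0.61 and a camera adjusted p = 4.3e-52. Of 39 genes of the NF-kB pathway and its feedback 14 rose and 0 fell (22 and 0 adjusted over the list alone, camera adjusted p = 9.9e-29), among them Nfkbia and Traf1. Of 23 cytokines and colony-stimulating factors 9 rose (10 adjusted over the list alone, camera adjusted p = 3.5e-12), including Il1b by 2.15, Csf2 by 1.54 and Tnf itself by 1.3. Of 19 matrix metalloproteinases and relatives 7 rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 2.2e-11). Of 20 genes of antigen presentation by MHC class I 7 rose (11 adjusted over the list alone, camera adjusted p = 5.6e-07). Leukocyte adhesion molecules were mixed, with 5 higher and 3 lower of 17 (5 and 6 adjusted over the list alone) and a median of 0.00, although the mean of 0.22 and the test pointed up (camera adjusted p = 2.2e-09). The 5 adhesion genes that rose include Vcam1 (2.27) and Icam1 (1.99), which weigh on that mean. These lists kept their calls with an estimated correlation.

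Proliferation genes rose by a small amount with TNF. Of 30 cell cycle genes 14 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.19, a camera adjusted p = 1.5e-13 and an adjusted p = 0.031 with an estimated correlation. Top2a, a topoisomerase of dividing cells, rose by 0.25. Tubular injury and failed repair genes, with 4 up and 4 down of 31 (7 and 9 adjusted over the list alone), had a median of -0.02 while the mean was 0.17 and the test pointed up (camera adjusted p = 0.00017, adjusted p = 0.10 with an estimated correlation). The 4 that rose include Vcam1 (2.27), Ccl2 (2.66) and Cxcl1 (1.03), so this is not a result apart from the adhesion and chemokine genes. For complement the call (2 higher of 17, camera adjusted p = 0.023) gave an adjusted p = 0.13 with an estimated correlation, although C3 rose by 1.08. The lists of apoptosis regulators, proximal tubule and fibroblasts also lost their calls there, at adjusted p = 0.094, 0.12 and 0.11 with an estimated correlation. Fry, which does not compare a list with other genes, called these lists and those of complement and tubular injury (fry adjusted p from 0.00057 to 0.0052). Interferon-stimulated genes had 4 higher and 2 lower of 36 (6 and 2 adjusted over the list alone) and no call as a list (camera adjusted p = 0.13). Macrophage and dendritic cell genes (median 0.10, camera adjusted p = 0.49) and genes of the unfolded protein response (camera adjusted p = 0.94) had no call as lists.

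**Figure D2:**
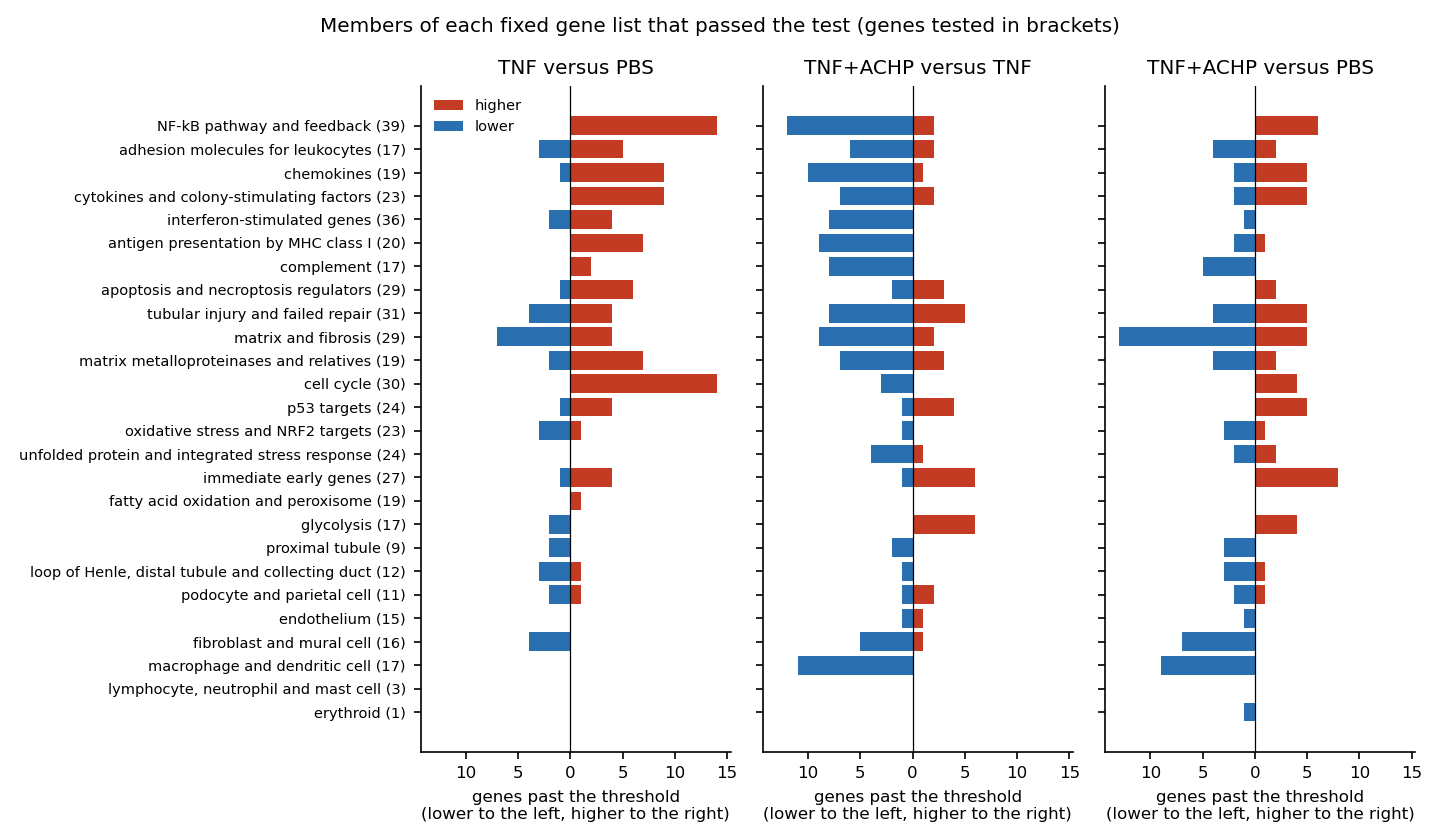
Number of genes of each fixed list that were higher (right) or lower (left) in each comparison at an edgeR adjusted p under 0.05, with the number tested in brackets. Chemokines, for example, have 9 higher with TNF and 10 lower with ACHP than TNF.

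ACHP returned the strongest TNF-induced genes toward the PBS level. Ccl2 was 16.4 ± 1.26 CPM with TNF and ACHP (SD, n = 3, log2 fold change against TNF -2.73, SE 0.06, edgeR adjusted p = 1.4e-16), and Icam1 was 9.39 ± 0.68 CPM (-1.87, SE 0.08, edgeR adjusted p = 4.9e-12). Tnfaip3 fell by 0.83, and Nfkbie, an inhibitor of NF-kB, also fell by 0.83. Mmp13, a collagenase, and Mmp12, an elastase, were lower with ACHP than with TNF and than with PBS: Mmp13 was 5.50 ± 1.65 CPM with PBS, 15.9 ± 1.72 with TNF and 2.33 ± 0.51 with TNF and ACHP, and Mmp12 was 10.7 ± 1.26, 22.7 ± 1.52 and 5.87 ± 0.90. Against PBS, Mmp13 differed by -1.24 (edgeR adjusted p = 0.0011), but by -0.66 with the term for neural transcripts described further on (edgeR adjusted p = 0.35). For Mmp3 the counts were 3, 1 and 1 with TNF and ACHP, and its change against TNF went from -5.20 to 0.19 with that term (edgeR adjusted p = 0.91). The size of the term comes from PBS replicate 1, where Mmp3 had no counts, so 0.19 is not a usable estimate. Of the 46 genes raised at least 2-fold by TNF, 37 were lower with ACHP than with TNF and 10 were still higher than with PBS. Their median log2 fold change was 1.43 for TNF versus PBS, -1.26 for ACHP versus TNF and 0.27 for ACHP versus PBS. The 46 genes were picked for high values in the TNF libraries, which ACHP versus TNF shares, so the 37 and the -1.26 lean toward a fall. Independent lists of these sizes would share 2.05 genes.

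Over all 488 genes raised by TNF, 223 were lower with ACHP, 4 were higher and 261 were called neither way. Of the 429 genes that TNF lowered, 114 were higher with ACHP than with TNF, among them Gdf15, a stress-induced cytokine (-0.45 with TNF, 0.65 with ACHP against TNF). With a neural library term, which marks the 5 libraries with the most neural transcripts, these overlaps were 71 and 26 genes. Both comparisons use the same TNF libraries, which ties them together. Independent lists of these sizes would share 21.8 and 11.6 genes, and 20 simulations with no change gave 0 to 1 genes in each direction. Neither value shows the overlap that shared TNF libraries give when many genes are called. Across all genes the covariance of both changes was -0.0246, against -0.0202 (-0.0217 to -0.0187) in those simulations, and their correlation was -0.17, weaker than the -0.50 (-0.54 to -0.48) that the shared libraries gave with no change. Without TNF replicate 1 the overlaps were 138 and 41 genes and without TNF replicate 2 they were 142 and 43. The second overlap was 74 without TNF replicate 3 and 67 without replicate 2 of TNF with ACHP.

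**Figure D3:**
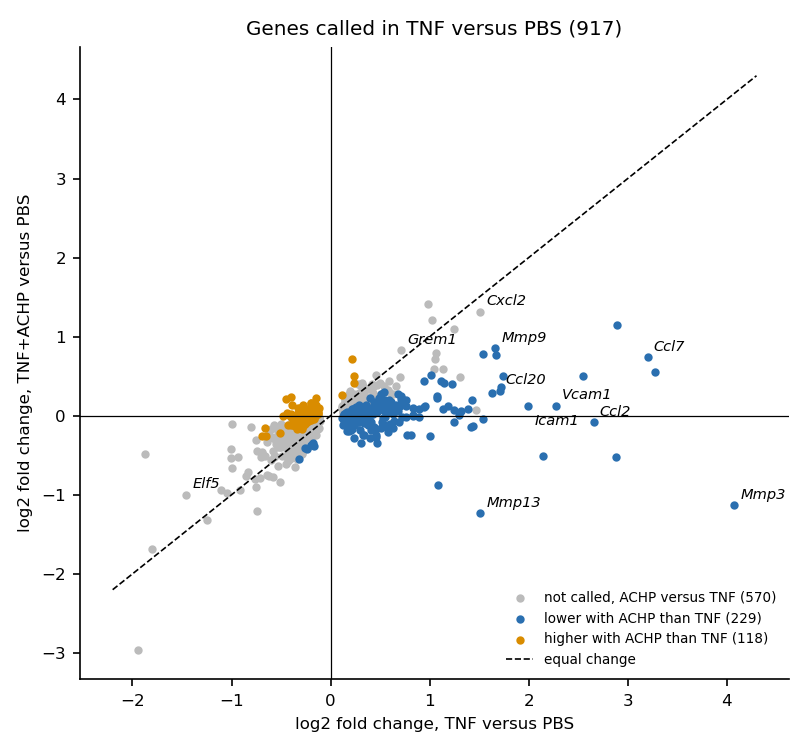
Log2 fold change against PBS of the 917 genes called with TNF, for TNF alone (horizontal) and TNF with ACHP (vertical), coloured by the call of ACHP versus TNF. Ccl2, Icam1 and Vcam1 lie near 0 on the vertical axis, whereas Cxcl2 and Grem1 lie close to the line of equal change.

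A smaller set of TNF-induced genes stayed high with ACHP. Cxcl2, a neutrophil chemokine, was 5.04 ± 0.65 CPM with PBS, 14.4 ± 1.28 with TNF and 12.5 ± 0.35 with TNF and ACHP (SD, n = 3), and differed from PBS by 1.32 (SE 0.11, edgeR adjusted p = 8.5e-07) and from TNF by -0.19 (SE 0.10, edgeR adjusted p = 0.28). Cxcl1, a related chemokine at low counts, differed from PBS by 1.03 with TNF and by 1.21 with ACHP. Grem1, an antagonist of bone morphogenetic proteins, went from 38.2 ± 0.68 to 62.4 ± 4.43 and 67.9 ± 1.99 CPM. Mmp9 kept part of its rise, at 101 ± 4.40 CPM, as did Nfkbia, at 50.0 ± 2.18 CPM. In all, 98 of the 488 genes were still higher than with PBS, and 80 of these were not lower with ACHP than with TNF. Of the genes lowered by TNF, 144 were also lower than PBS with ACHP, among them Elf5 (-1.0) and Ggt1 (-0.52). With the neural library term 17 genes were higher and 36 lower than PBS in both comparisons. Cxcl1 and Elf5 kept most of their change for ACHP versus PBS with it, at 1.07 and -0.88, but had no call (edgeR adjusted p = 0.089 and 0.10). Both comparisons use the same PBS libraries. Independent lists would share 10.6 and 16.6 genes, and the 20 simulations with no change gave 0 to 1 genes higher and 0 lower in both. Neither value shows the overlap that shared PBS libraries give when many genes are called.

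Some genes that were not called with TNF alone rose when ACHP was present. Clca3b, of a family of secreted channel regulators, was 22.3 ± 2.22 CPM with PBS, 21.7 ± 0.82 with TNF and 53.5 ± 2.95 with TNF and ACHP (SD, n = 3, log2 fold change against TNF 1.3, SE 0.07, edgeR adjusted p = 1.7e-10). Sprr1a, a gene of stressed and keratinising epithelium, rose by 0.82 against TNF, Crct1 by 0.84 and Cebpd, an inflammatory transcription factor, by 0.77. Map3k14, the kinase of the non-canonical NF-kB pathway, rose by 0.65 against TNF and by 0.53 against PBS. Cxcl5, a neutrophil chemokine, had 41, 34 and 40 counts with TNF and 67, 236 and 170 with TNF and ACHP. Il11 was 36.0 ± 1.82, 41.8 ± 0.64 and 59.1 ± 1.41 CPM in the 3 groups, so its mean was above PBS with TNF alone as well. In total 102 genes were higher with TNF and ACHP than in both other groups, and 92 of them were not called for TNF versus PBS, but with the neural library term these were 11 and 8 genes. With no group treated with ACHP alone, an effect of ACHP that needs no TNF is not separable here.

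Transcripts of macrophages were much lower with ACHP than in both other groups. Lyz2, which encodes lysozyme, was 6.59 ± 0.52 CPM with PBS, 8.82 ± 1.19 with TNF and 1.11 ± 0.49 with TNF and ACHP (SD, n = 3, log2 fold change against TNF -2.95, SE 0.21, edgeR adjusted p = 1.7e-08). C1qa, a subunit of the complement initiator C1q, had 31, 34 and 25 counts with PBS, 36, 11 and 22 with TNF and 2, 3 and 1 with TNF and ACHP. C1qb fell by 3.07 and C1qc fell by 3.23. Of 17 macrophage and dendritic cell genes tested 11 were lower than with TNF and 0 higher (12 and 0 adjusted over the list alone), with a median of -1.89, a camera adjusted p = 2.1e-16 and an adjusted p = 0.0016 with an estimated correlation. Against PBS 9 were lower, with a median of -1.21. With the neural library term 3 of the 17 were called lower than with TNF and 5 lower than with PBS, and C1qc moved from -3.23 to -3.26 with a wider error (SE 0.54 to 0.85, edgeR adjusted p = 0.072). Csf1r, the receptor for macrophage growth factor, fell by 0.55, and Tgfbi fell by 2.58. Complement as a list fell with the C1q genes it contains, with 8 of 17 lower (12 adjusted over the list alone, camera adjusted p = 2.0e-12).

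Inflammatory lists went down with ACHP relative to TNF. Of the chemokines 10 were lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 5.9e-39), of the NF-kB genes 12 and 2 (15 and 3 adjusted over the list alone, camera adjusted p = 1.5e-11), and of the adhesion molecules 6 and 2 (7 and 5 adjusted over the list alone, camera adjusted p = 1.1e-12). The 6 adhesion molecules include Vcam1 (-2.15) and Icam1 (-1.87). Of the cytokines 7 were lower and 2 higher (10 and 2 adjusted over the list alone, camera adjusted p = 1.8e-06), among them Il1b (-2.66) and Tnf (-1.29). Macrophage transcripts fell in the same comparison (list median -1.89), and the counts do not show which cells made Il1b and Tnf. A loss of macrophage RNA is therefore not separated from a reversal of the TNF effect for these cytokines. MHC class I presentation had 9 lower of 20 (10 adjusted over the list alone, camera adjusted p = 1.3e-06), including Erap1 by -0.38, and the metalloproteinases had 7 lower and 3 higher of 19 (8 and 4 adjusted over the list alone, camera adjusted p = 6.2e-10). All of these kept their calls with an estimated correlation. With the neural library term fewer members were called lower: 4 chemokines, 8 NF-kB genes, 3 adhesion molecules, 1 cytokine, 1 MHC class I gene and 4 metalloproteinases. The lists themselves kept their calls with it. Interferon-stimulated genes had 8 lower of 36 (10 lower and 2 higher adjusted over the list alone, camera adjusted p = 3.4e-05), with an adjusted p = 0.19 with an estimated correlation and a fry adjusted p = 0.025, and Ddx58, an RNA sensor, fell by 0.48.

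Some glycolysis and immediate early genes rose with ACHP, without a call for either list at an estimated correlation. Of 17 glycolysis genes 6 were higher than with TNF and 0 lower (7 and 0 adjusted over the list alone, median 0.11, camera adjusted p = 6.1e-06), with an adjusted p = 0.22 with an estimated correlation. Of 27 immediate early genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.00016), with an adjusted p = 0.14 with an estimated correlation, and Dusp1, a phosphatase that limits MAP kinases, rose by 0.46. Fatty acid oxidation genes had no call as a list (median 0.00, camera adjusted p = 0.91). Jund, with 52.6% of its exon length shared with other genes, rose by 0.35. Matrix genes had 9 lower and 2 higher of 29 (12 and 3 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation), and the list of tubular injury had 8 lower and 5 higher of 31 (9 and 9 adjusted over the list alone), with a median of 0.01 but a mean of -0.14 and a test that pointed down (adjusted p = 0.094 with an estimated correlation). The 8 tubular injury genes include Vcam1 (-2.15) and Ccl2 (-2.73). Cell cycle genes, 3 lower of 30 (8 adjusted over the list alone), and fibroblast genes, 5 lower and 1 higher of 16 (7 and 1 adjusted over the list alone), had an adjusted p = 0.27 and 0.14 with an estimated correlation. Fry called the glycolysis, immediate early, matrix, tubular injury, cell cycle and fibroblast lists (fry adjusted p from 0.0021 to 0.032). With the neural library term the members called were 1 glycolysis gene and 2 immediate early genes higher, and 1 matrix gene, 2 tubular injury genes, 1 cell cycle gene and 0 fibroblast genes lower.

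Relative to PBS, cultures with TNF and ACHP had fewer transcripts of stroma and proximal tubule. Col1a2, a fibrillar collagen, went from 79.7 ± 1.35 to 59.4 ± 0.77 CPM (SD, n = 3, log2 fold change -0.42, SE 0.04, edgeR adjusted p = 9.6e-06), and Acta2, the smooth muscle actin of myofibroblasts, fell by 0.37. Of 16 fibroblast and mural cell genes 7 were lower and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 3.5e-09), and of 29 matrix genes 13 were lower and 5 higher (14 and 7 adjusted over the list alone, camera adjusted p = 2.2e-06). Of 9 proximal tubule genes 3 were lower (5 adjusted over the list alone, camera adjusted p = 1.4e-05), among them Ass1 (-0.22) and Slc4a4 (-0.25). NF-kB genes had 6 higher and 0 lower (9 and 1 adjusted over the list alone, camera adjusted p = 1.1e-05), p53 targets 5 higher and 0 lower of 24 (7 and 0 adjusted over the list alone, camera adjusted p = 0.0012) and immediate early genes 8 higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 3.0e-09). These lists and the lower macrophage and complement lists kept their calls with an estimated correlation and with the neural library term. ACHP versus PBS with that term rests on PBS replicate 1 as the only PBS library, so it is no check over all 9 libraries. Fewer members were called with that term: 3 fibroblast genes, 5 matrix genes and 2 proximal tubule genes lower, and 1 matrix gene, 3 NF-kB genes, 1 p53 target and 4 immediate early genes higher. Ass1 had no call with it (edgeR adjusted p = 0.12). The cytokines had 5 higher and 2 lower of 23, a median of -0.01 and a test that pointed up (camera adjusted p = 0.042, adjusted p = 0.11 with an estimated correlation, camera adjusted p = 0.27 with the neural library term). Chemokines had 5 higher and 2 lower of 19 and a camera adjusted p = 0.069, which became a call up with the neural library term (camera adjusted p = 0.019, 2 members higher and 0 lower) and with total counts alone (camera adjusted p = 0.048).

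Transcripts of neurons were much more abundant in 5 of the 9 libraries, and the 3 PBS libraries fell on both sides. The other 4 libraries held few of them and are counted here as libraries without neural transcripts. The summed expression of 23 neuron genes, a list written after this was seen, was 3.59, 128.3 and 91.1 CPM in PBS replicates 1, 2 and 3, 42.8, 74.1 and 56.9 CPM in the TNF libraries and 4.62, 3.35 and 3.49 CPM with TNF and ACHP. Camk2a, a kinase of synapses, had 1, 400 and 406 counts with PBS, 146, 300 and 278 with TNF and 8, 2 and 4 with TNF and ACHP. Slc1a2, a glutamate transporter of astrocytes, had 10, 704 and 670 counts, then 301, 501 and 419, then 37, 23 and 8. Genes at least 4-fold higher in PBS replicates 2 and 3 than in PBS replicate 1 (after adding 0.25 CPM) numbered 140 among the genes tested, and 0 were at least 4-fold higher in replicate 1. They made up between 0.0026% and 0.0545% of the counts of a library.

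**Figure D4:**
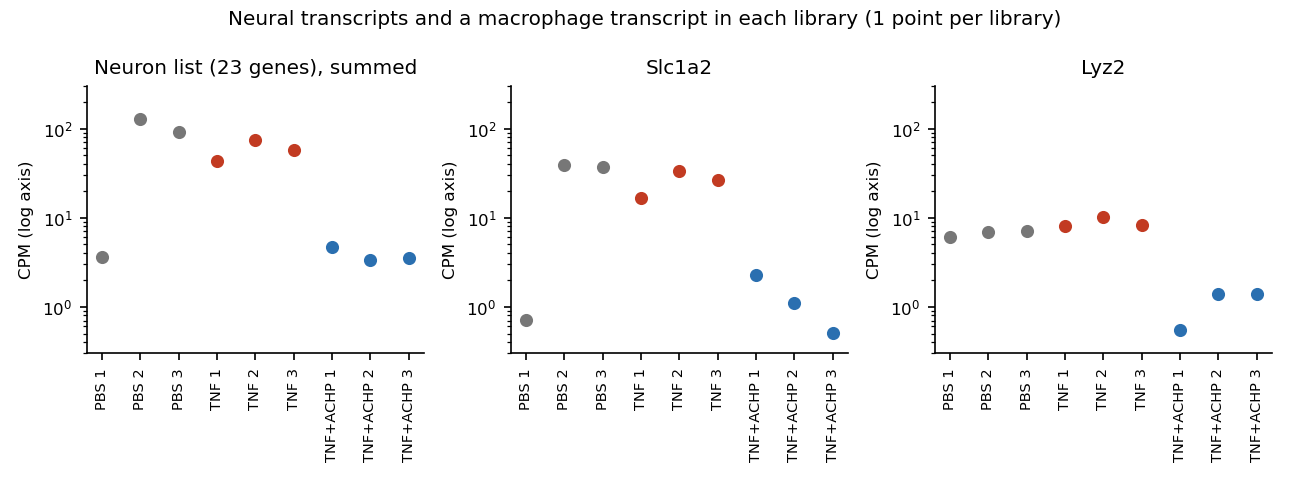
CPM (of total counts, without TMM) on a log axis of 23 neuron genes summed, of Slc1a2 and of Lyz2 in each of the 9 libraries, 1 point per library. PBS replicate 1 lies with the libraries of TNF and ACHP for the neuron genes and Slc1a2, and with the other PBS libraries for Lyz2.

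The genes that follow the neural transcripts weigh on the comparisons with ACHP, because all 3 TNF libraries hold many more neural transcripts than the 3 libraries with ACHP. By edgeR 400 genes were higher and 658 lower with ACHP than with TNF, 3 and 231 of them by at least 2-fold. Of the 658, 99 were among the 140 genes that follow the neural transcripts, which leaves 559. Against PBS 321 were higher and 570 lower, 10 and 235 of them by at least 2-fold. Of the 570, 119 were among the 140 genes, which leaves 451. With a term for the libraries that hold neural transcripts, the numbers were 44 and 99 for ACHP versus TNF and 53 and 109 for ACHP versus PBS, and Vcam1 then fell by 2.10 with ACHP (edgeR adjusted p = 6.8e-08, between 7.1e-252 and 6.8e-08 over the alternatives tried). The size of the term comes from PBS replicate 1 against PBS replicates 2 and 3, so both comparisons with ACHP then rest on PBS replicate 1. It also treats the 5 libraries as alike, although the neuron list was 42.8 to 74.1 CPM with TNF and 128.3 and 91.1 CPM in PBS replicates 2 and 3. For genes that follow the neural transcripts it can therefore take away too much in ACHP versus TNF. No comparison of ACHP with TNF can be made within either kind of library. For TNF versus PBS among the libraries that hold neural transcripts (without PBS replicate 1) there were 479 higher and 478 lower. For ACHP versus PBS among the libraries without them, PBS replicate 1 is the only PBS library, and 89 genes were higher and 148 lower. Lyz2, C1qa, Ccl2, Icam1 and Tnfaip3 stayed lower with ACHP than TNF with this term, at -2.75, -3.97, -2.67, -1.99 and -0.83. Some genes kept their direction but not their call: Il1b moved from -2.66 to -2.31 (SE 0.85, edgeR adjusted p = 0.25), Tnf from -1.29 to -0.90 (SE 0.48, edgeR adjusted p = 0.46), Cebpd from 0.77 to 0.89 (SE 0.27, edgeR adjusted p = 0.13) and Cxcl5 from 1.90 to 1.43 (SE 0.58, edgeR adjusted p = 0.31). Ccl7 moved further, from -2.46 to -1.45 (SE 0.94, edgeR adjusted p = 0.56). Calls were also lost by the interferon, matrix and fibroblast lists (camera adjusted p = 0.36, 0.15 and 0.42).

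The numbers of genes in the comparisons with ACHP also moved with single libraries. For ACHP versus TNF they were 181 higher and 422 lower without TNF replicate 1, 157 and 384 without TNF replicate 2, 258 higher without TNF replicate 3, 188 and 402 without replicate 2 of TNF with ACHP, and 212 and 431 without its replicate 3. For ACHP versus PBS they were 154 and 357 without PBS replicate 2 and 134 and 360 without replicate 3 of TNF with ACHP. Any difference among the 3 groups was found for 1688 genes by edgeR, and the unadjusted p was under 0.05 for 3752.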

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

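The neural library term and the neural score covariate were chosen after the data were seen. So were the omission of the genes that follow the neural transcripts and the use of PBS replicate 1 alone. All other alternatives were chosen before. Vcam1 kept its calls and directions for TNF versus PBS and for ACHP versus TNF under every alternative run, and had no call for ACHP versus PBS under any of them (adjusted p 0.30 to 0.96). Leaving out a library gave log2 fold changes for Vcam1 of 2.21 to 2.33, -2.26 to -2.07 and 0.01 to 0.20. Leaving out a library gave 252 to 502 genes higher and 216 to 478 lower for TNF versus PBS, 157 to 527 and 384 to 824 for ACHP versus TNF, 134 to 427 and 357 to 731 for ACHP versus PBS, and 1133 to 1850 with any difference. Genes up with TNF and down with ACHP numbered 138 to 228, and those down then up 41 to 117.

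The numbers of genes stayed within 1.5 times the reported ones with DESeq2, RLE factors, total counts alone, the stricter filter, the replicate block and thinned counts. The same held for the omission of the genes that follow the neural transcripts. DESeq2 called 413 higher and 352 lower for TNF versus PBS, and 387 of the 413 were also called by edgeR. With replicate number as a block the numbers were 512 and 433, 443 and 732, and 372 and 616. Whether the replicate numbers pair the libraries is not settled: 4 of the 9 libraries correlated best with libraries of their own number. Correlations ran from -0.10 to 0.17 between libraries of the same number and from -0.21 to 0.17 between libraries of different numbers. Without a filter ACHP versus PBS had 862 lower genes, with 30465 genes tested. Fitted on its 6 libraries alone, ACHP versus PBS had 148 higher and 345 lower. The cause was not tested.

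A stricter threshold lowers counts by construction. At an adjusted p under 0.01 there were 248 higher and 194 lower for TNF versus PBS, 147 and 321 for ACHP versus TNF, 111 and 316 for ACHP versus PBS, 814 with any difference, and overlaps of 126 and 37. With an absolute log2 fold change of at least 1 these were 46 and 9, 3 and 231, 10 and 235, and overlaps of 28 and 0. Of the 78 list tests 23 were called with an estimated correlation against 42.

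The neural library term left TNF versus PBS at 489 higher and 464 lower and gave 44 and 99 for ACHP versus TNF, 53 and 109 for ACHP versus PBS, 894 with any difference, and overlaps of 71 and 26. The neural score covariate gave 65 and 139, 48 and 104, 897, and overlaps of 91 and 25. Both share most of the contrast of ACHP with TNF, so errors widen: the median SE of the genes lower with ACHP than TNF went from 0.075 to 0.142 with the term. With PBS replicate 1 as the only PBS library there were 277 higher and 141 lower for TNF versus PBS, 89 and 148 for ACHP versus PBS, 610 higher for ACHP versus TNF and 52 genes down then up. This leaves a lone PBS library, and with the neural library term ACHP versus PBS rests on that library as well.

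Of 215 values for named genes, 187 of the 211 that DESeq2 gave kept direction and call, and 24 lost the call. With the neural library term 123 kept both, 85 lost the call and 7 changed sign, counting a sign only where at least 1 of the fits had a call. For ACHP versus TNF these were Snap25 (0.96), Camk2a (2.36), Gpm6a (1.44), Slc1a2 (1.43), Sparcl1 (0.98) and Mmp3 (0.19), and for ACHP versus PBS Hbb-bs (3.12). Hbb-bs for ACHP versus TNF, without a call in either fit, went from -3.62 to 4.44. The neural score covariate turned Gpm6a (0.18) and Slc1a2 (0.094). With PBS replicate 1 as the only PBS library Hbb-bs turned for TNF versus PBS (6.71) and ACHP versus PBS (3.09). Snap25, Camk2a, Gpm6a, Slc1a2, Sparcl1 and Hbb-bs are among the genes the term was built to absorb. The TNF libraries held fewer neural transcripts than PBS replicates 2 and 3, so for such genes the term can take away too much in ACHP versus TNF. Mmp3 had 0 to 8 counts outside the TNF libraries and none in PBS replicate 1, on which the term rests. Its value with the term is therefore not a usable estimate.

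Depth limits what can be said of genes such as C1qa and Mmp3, at 1 to 3 counts per library with ACHP. The SE of their log2 fold changes against TNF was 0.53, against 0.08 for Vcam1.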

Other observations

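The tests of neural and macrophage transcripts in this part were chosen after the result was seen, and the splits of the libraries before. Of the genes of the endoplasmic reticulum stress response, 2 chaperones were lower with ACHP while the list was not, and 0 members of the list were called with the neural library term. Calr, a calcium-binding chaperone, was 1122 ± 43.3 CPM with PBS, 1119 ± 11.3 with TNF and 975 ± 40.8 with TNF and ACHP (SD, n = 3, log2 fold change against TNF -0.20, SE 0.04, edgeR adjusted p = 0.0015), and the change was -0.21 with the term (edgeR adjusted p = 0.16). Hsp90b1, another chaperone with 15.7% of its exon length shared with other genes, fell by 0.25, and by 0.31 with the neural library term (edgeR adjusted p = 0.087). The list of 24 genes had 4 lower and 1 higher (5 and 5 adjusted over the list alone), a median of 0.03 and no call as a list (camera adjusted p = 0.91). Txnrd1, a thioredoxin reductase, fell by 0.17, and by 0.16 with the term but without a call (edgeR adjusted p = 0.28).

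Most markers of the mature proximal tubule were too low to test in these cultures: 9 of 28 passed the filter. Those that did included Ass1, at 141 ± 2.35 CPM with PBS, and Slc4a4, at 124 ± 1.64 CPM. Cldn1, a junction gene of parietal cells, was 519 ± 5.02 CPM with PBS and 611 ± 14.9 with TNF and ACHP.

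Other splits of the same libraries were tested for each count of genes. For TNF versus PBS the real split of the 6 libraries, fitted alone, called 940 genes and the highest of the others 0. For ACHP versus TNF it was 1380 against 0 and for ACHP versus PBS 493 against 4. In each of these comparisons 1 of 10 splits was as high as the real split, itself, and 10 splits are too few for a share under 0.05. Of 100 splits drawn from the 280 of all 9 libraries into 3 groups, 1 gave as many genes with any difference as the real split, itself (1688 against at most 285). For genes up with TNF and down with ACHP it was also 1 of 100 (223 against at most 126), and for genes down then up 1 of 100 (114 against at most 37). A share of 1 in 100 is the lowest that this number of splits can give. Most other splits mix treatments within groups, which widens the spread and lowers their counts. A difference between cultures or batches that runs along the groups is not excluded. The highest other split for both overlaps kept the 3 TNF libraries together.

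Neural transcripts in 5 of the 9 libraries were weighed first. Treatment does not account for the difference among the PBS libraries, where replicates 2 and 3 had at least 25.3 times the neuron list expression of replicate 1. That rests on 1 library, in which the pattern was first seen. All 3 TNF libraries were high (42.8 to 74.1 CPM) and all 3 with ACHP low (3.35 to 4.62 CPM), so a part played by treatment is not excluded. RNA or reads from brain tissue may be the source: 14 of 22 astrocyte and oligodendrocyte genes were higher in each of the 5 libraries than in each of the 4 others. The 5 libraries were picked on neural transcripts and the genes are not independent, so this count has no chance level to be set against. The gap was small for some of the 14, such as Mbp (at least 93.7 against at most 91.3 CPM), and 9 of the 22 exceed 1 CPM in the 4 libraries without neural transcripts. Slc1a2 was at least 16.4 CPM in the 5 libraries and at most 2.25 CPM in the 4. Whether this came from the cultures, the RNA, the library preparation or the sequencing cannot be read from the table. No biological explanation other than treatment was tested.

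Genes lower with ACHP than TNF, other than those that follow the neural transcripts, were weighed next. If RNA or reads from brain tissue made them lower, a term for the 5 libraries would bring their median to near 0. The median of the 559 genes was -0.41 without the term and -0.35 (-0.345) with it, and 96.6% kept their sign. These values are against this source for the remaining genes as a set. They do not speak for the genes left out beforehand, which the term would move most, and they rest on PBS replicate 1, which sets its size. Most of the 559 genes lost their call, as the median SE rose from 0.075 to 0.142. Single genes stay open, such as Rtn1, which is abundant in neurons and differed by -2.07 between ACHP and TNF without reaching the 4-fold limit, but by -0.34 with the term (SE 0.36, edgeR adjusted p = 0.76).

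Macrophage transcripts were weighed last. RNA or reads from brain tissue, which holds microglia, would lower them in PBS replicate 1, but the median log2 ratio of PBS replicate 1 to PBS replicates 2 and 3 over the 11 called markers was -0.19 (-0.193, from -0.85 to 0.74). A lower share of all cells other than tubule cells would lower stroma and endothelium as far, but the lower of their medians was -0.19 (-0.192) against -1.89 for macrophages. Fewer macrophages would lower all macrophage genes by a like factor, and the 11 markers differed by more than their errors (chi-square per degree of freedom 19.5). Without Csf1r, Aif1 and Cd74, which other cells also make and which were set aside after their values were seen, it was 1.70 over 8 markers (-3.54 to -1.89), so a loss of macrophages and less RNA of these genes per macrophage cannot be told apart. Ptprc, found on all leukocytes and picked after its value was seen, fell by 0.65 without a call (edgeR adjusted p = 0.12).

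Transcripts of the liver appeared in a single library. The 16 genes of the liver list summed to 9.38 CPM in replicate 2 of TNF with ACHP and to between 0.608 and 1.15 CPM in the other 8 libraries. Alb, the albumin gene, also picked after its values were seen, had 77 counts there and at most 1 elsewhere. The lists of pancreas (0.383 to 0.930 CPM), lung (0.790 to 1.62), intestine (1.24 to 2.73), testis (2.39 to 5.21), muscle (102.1 to 143.3) and choroid plexus (7.17 to 22.6) set no other library apart to that extent.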
